A study of Drosophila melanogaster with 16 samples.

How the data were processed

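The measurements were read counts from chromatin immunoprecipitation and sequencing (ChIP-seq) of nuclei taken from adult Drosophila heads, with positions on the dm3 assembly. The values deposited by the authors were raw counts per annotated isoform, in 1001 bp promoter windows for H3K4me3, H3K27ac and their inputs, and over gene bodies for H3K27me3 and its inputs. According to the submitters' processing notes, base calling used CASAVA 1.8, alignment used Bowtie 0.12.7 and counting over features used bedtools 2.15. The treatment of reads with several matching places in the genome was not given in the sources used here, so values for close paralogs and overlapping genes carried that uncertainty. A table of counts in 10 kb windows with a 5 kb step, which held OK107 and Tdc2 but not R57C10, was used for regions.

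Of 25701 isoform entries, 25406 had a gene, and 203 isoforms without one held 0.463 to 1.16% of the counts of a column. The 92 spike-in control entries held 0 counts. For each of 15182 genes the isoform with the largest sum over the libraries of a mark was kept; 268 genes were known by identifier only. Another 61 sample columns of the same tables were not used here.

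Each mark was fitted with edgeR 4.0.16 in R 4.3.3, using quasi-likelihood tests, TMM scaling, the default expression filter and all driver lines of the mark in a single model. Genes passed at a false discovery rate of 0.05 across all tested genes of a comparison. The fit kept 14585 genes for H3K27me3, 14732 for H3K4me3 and 14710 for H3K27ac, and left out 597, 450 and 472. Residual degrees of freedom were 2, 1 and 1 and common dispersions were 0.02, 0.199 and 0.024. Errors of log2 folds are standard errors from the fit, errors of levels are standard deviations between libraries, and levels of marks are TMM-scaled CPM. Inputs are CPM by total count without TMM scaling, so marks and inputs are not on exactly the same scale. Single libraries were assumed to vary as much as the replicated groups. The labels did not say whether replicates came from separate preparations, so p-values measured only the spread between these samples, which may be technical.

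Named sets of genes were tested with the camera test of limma 3.58.1, with its preset correlation of 0.01, and adjusted over the lists of a comparison. A correlation estimated from the data was an alternative, and no list passed with it in any comparison. That alternative uses the residual degrees of freedom of the fit, only 2, 1 and 1, so it had little power. A list that did not pass with it is therefore not shown to be unchanged. The 21 lists were written from general knowledge before the data were examined. They covered octopaminergic genes, Kenyon cell genes, pan-neuronal genes, glia, photoreceptors, muscle with fat body and blood, cholinergic genes, GABAergic genes, other monoamines, neuropeptides, Hox and segmentation genes, neural progenitors, homeodomain identity genes, ion channels, odorant receptors, gustatory receptors, ionotropic receptors, ribosomal proteins, germline genes, sex-limited genes and transgene loci. The transgene loci were w, Tdc2, n-syb and ey, because driver constructs can carry or disturb these genes. Lists of fewer than 3 tested genes were described without a test. Members were also tested with adjustment over the list alone.

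Genes were named by a rule. All octopaminergic, Kenyon cell and transgene loci members were eligible in every comparison. To these were added the 10 largest called folds in each direction among genes above the median level, with libraries that did not overlap and a symbol other than a bare number. Up to 4 members of each other list were added, called genes first by size of fold and then by level. Any gene outside this rule was chosen after its values were seen, and this applies to every gene named for windows, for promoters of OK107 against Tdc2 and for pairs of marks.

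The alternatives set out at the start were RLE and total count scaling, DESeq2 1.42.0, a model with the 2 compared lines only, an offset from the inputs, the isoform with the largest input, and leaving out each replicate. Alternatives added after the data were seen were loess scaling along promoter or gene level, loess scaling along enrichment, restriction to the large arms and chromosome 4, and a running median along level for single libraries. In the scaling by enrichment, the trend of the fold on the log2 ratio of mark to input in the line outside the comparison was removed. A real change that runs along enrichment is removed with it, so lists at either end of enrichment lose their fold in either case. For OK107 against Tdc2 in H3K4me3 and H3K27ac, with 1 library on each side, no test was made. Differences were set against the 99th percentile of differences between the R57C10 replicates.

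List levels were compared with 10000 random lists of the same size matched on input in 20 bins, with a pseudocount of 1.0. The fitting steps were checked on simulated counts, with 200 altered genes, 100 at 2-fold and 100 at 4-fold. These counts used the real library sizes and the common dispersion of the mark for every gene. Lines did not differ in enrichment there, so the recovery rates need not hold for the real data. False calls among unaltered genes ranged from 0 to 15 in a comparison. Genes with no reads in a whole group were given a floor of 3 counts over that group. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used for tables, windows and figures. Base composition was not analysed here.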

Results

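Chromatin was profiled in neurons of adult Drosophila heads with antibodies against H3K4me3 and H3K27ac, which mark active promoters, and H3K27me3, which marks Polycomb-repressed genes. Nuclei carrying a GFP-tagged envelope protein were captured from 3 GAL4 driver lines, and their chromatin was cut with micrococcal nuclease. R57C10 labels all mature neurons, OK107 labels primarily Kenyon cells, the intrinsic neurons of the mushroom body, and Tdc2 labels primarily octopaminergic neurons. R57C10 had 2 libraries for each mark, called early and late here by the date tag in their names. OK107 had 1 library for each mark, and Tdc2 had 1 library for H3K4me3 and H3K27ac and 2 for H3K27me3. Each line had 1 input library, counted at promoters and over gene bodies.

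Reads in H3K27me3 gene bodies numbered 45.77 and 36.28 M for R57C10 early and late, 54.75 M for OK107, and 8.54 and 7.77 M for Tdc2 early and late. H3K4me3 promoters held 13.88 and 46.64 M in R57C10, 42.15 M in OK107 and 6.01 M in Tdc2. H3K27ac promoters held 17.2 and 10.05 M in R57C10, 11.1 M in OK107 and 7.95 M in Tdc2. The inputs held 45.64 M in R57C10, 56.09 M in OK107 and 51.03 M in Tdc2 over gene bodies, and 7.24, 8.43 and 8.06 M at promoters in the same order. The R57C10 libraries had other date tags than OK107 and Tdc2 in every mark and in the inputs, so driver and date tag were confounded in comparisons with R57C10. OK107 and Tdc2 shared a tag in H3K4me3 and H3K27ac, and OK107 shared one with early Tdc2 in H3K27me3.

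Across genes, which are not independent replicates, R57C10 replicates correlated at 0.995 in H3K27me3, 0.982 in H3K4me3 and 0.959 in H3K27ac, and the Tdc2 replicates correlated at 0.968 in H3K27me3. The median absolute log2 difference between R57C10 replicates was 0.15, 0.78 and 0.22, and 0.24 between Tdc2 replicates. In H3K4me3 the difference of early minus late ran from 1.03 in the lowest 20% of promoters to -0.67 in the highest 20%.

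The question for OK107 against R57C10 in H3K27me3 was which genes differ in Polycomb marking between Kenyon cells and all neurons, with 1 and 2 libraries. The gene eyeless (ey, CG1464, chromosome 4, 718315 to 741787), a Pax6 transcription factor required for mushroom body development, had the largest fall of the named genes, with log2 fold -3.39 ± 0.25 and adjusted p = 2.0e-04. Its level was 159 CPM in OK107 and 1660 ± 400 CPM in R57C10, with inputs of 174 and 301 CPM. OK107 is inserted near ey, so the input stands beside this value. The second Pax6 gene, twin of eyeless (toy, CG11186, chromosome 4, 1010354 to 1026929), fell by 1.15 ± 0.22 log2 (332 against 735 ± 197 CPM, adjusted p = 0.021). The median log2 ratio of the OK107 gene-body input to that of R57C10 on chromosome 4 was -0.55, below 0 for 83 of 84 genes.

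Kenyon cell genes had a median log2 fold of -0.47, with 3 of 25 lower and 0 higher over all genes and 13 lower when adjusted over the list alone (adjusted p = 7.9e-12). The same test gave adjusted p = 0.671 with an estimated correlation. Eip93F (CG18389, 3R, 17774836 to 17832525), an ecdysone-induced transcription factor, was the other Kenyon cell gene that fell (-0.79 ± 0.17, 380 against 654 CPM, adjusted p = 0.037). DopR2, a dopamine receptor, had -0.78 (adjusted p = 0.052), and jdp, dac and pros had -0.77, -0.72 and -0.67 without passing. Pan-neuronal genes had a median of 0.31 with 0 called over all genes, and 4 higher and 1 lower adjusted over the list alone (adjusted p = 1.2e-04). Their median log2 ratio of H3K27me3 to input was below 0 in OK107 (-0.62) and in R57C10 (-1.02 and -1.13). Cholinergic genes had 0.45 (0.0070), ionotropic receptors 0.15 (0.0016) and ribosomal proteins -0.14 (0.020); all 4 lists had adjusted p = 0.671 with an estimated correlation.

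**Figure D1:**
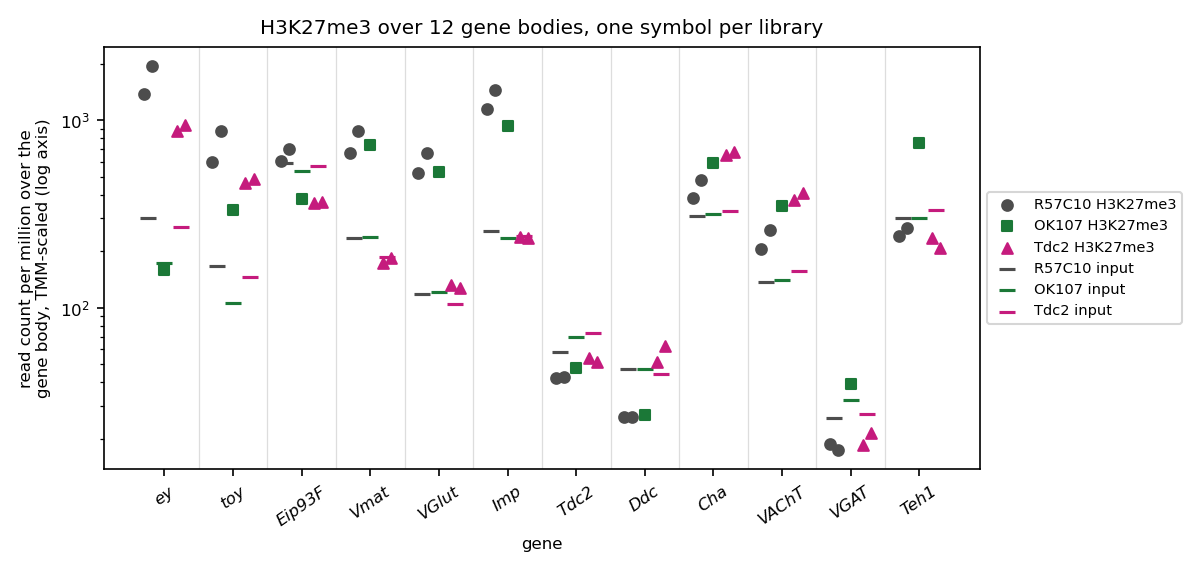
H3K27me3 over gene bodies in TMM-scaled CPM on a log axis for 12 genes, with a symbol for each library of R57C10, OK107 and Tdc2. Dashes are the inputs, in CPM without TMM scaling. The level of ey lies near its input in OK107 only, and those of Imp, VGlut and Vmat lie near their inputs in Tdc2 only.

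In this comparison 319 of 14585 genes were called, 229 higher and 90 lower. Teh1 (CG12806, 3R, 5653580 to 5693842), a sodium channel accessory subunit, rose by 1.58 ± 0.16 (760 against 255 ± 17.6 CPM, adjusted p = 0.0012), with inputs of 301 and 302 CPM. Dhc36C, a dynein heavy chain, rose by 1.44 (1020 against 376 CPM), hbs, an adhesion protein (CG7449, 2R, 10898903 to 10928901), by 1.33 (891 against 356 CPM), and eloF, a fatty acid elongase, by 1.34. The vesicular GABA transporter VGAT (CG8394, 2R, 10086505 to 10088226) rose by 1.12 ± 0.21 (39.2 against 18.1 CPM, adjusted p = 0.016). The Y-linked dynein gene kl-2 rose by 1.29, RhoGEF3 by 1.38, the progenitor factor cas by 1.15 and the gustatory receptor Gr21a by 0.85. The neighbouring ionotropic receptors Ir94a, Ir94b and Ir94c rose by 1.08, 1.07 and 1.07.

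Among lower genes were Dat (CG3318, 2R, 20027108 to 20045285), a dopamine N-acetyltransferase (-1.69 ± 0.21, 114 against 367 CPM, adjusted p = 0.0033), and Hr51, a nuclear receptor (CG16801, 2R, 11219106 to 11226825; -1.16, 238 against 530 CPM). The nicotinic receptor subunits nAcRalpha-34E and nAcRalpha-30D fell by 1.25 (335 against 796 CPM) and 1.24 (762 against 1800 CPM), and the glutamate receptor Glu-RI by 1.49. KCNQ, a potassium channel, and the odorant receptors Or45a, Or85b and Or85c had -0.91, -1.35, -1.16 and -1.02.

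The remaining lists did not pass. Hox and segmentation genes had a median of -0.03 with 0 called, and Antp, Ubx and Abd-B had 0.02, -0.03 and 0.00. Homeodomain genes had -0.10 with 1 higher (adjusted p = 0.051), and octopaminergic genes 0.17 with 0 called and 1 higher adjusted over the list alone. The median was positive and the test negative for odorant receptors (0.05, mean -0.08), transgene loci (0.13, mean -0.70) and muscle, fat body and blood genes (0.03, mean -0.02), while neural progenitor genes had median -0.04 and mean 0.07. The calls were 508 higher and 143 lower without R57C10 late but 274 higher and 573 lower without R57C10 early, so the balance of directions turned with 1 library, and their number was 993 without Tdc2 early and 990 without Tdc2 late, and 146 with RLE and 634 with total count scaling. On simulated data of this comparison the fit recovered 57% of 2-fold and 100% of 4-fold changes.

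Polycomb marking in octopaminergic neurons was asked by Tdc2 against R57C10, with 2 libraries each. The vesicular monoamine transporter Vmat (CG33528, 2R, 9400632 to 9420494), which loads octopamine into vesicles, fell by 2.12 ± 0.16 (179 ± 8.39 against 776 ± 148 CPM, adjusted p = 4.0e-05). The vesicular glutamate transporter VGlut (CG9887, 2L, 2400295 to 2410662) fell by 2.21 ± 0.15 (129 ± 3.35 against 600 ± 104 CPM, adjusted p = 2.5e-05). The RNA-binding protein gene Imp (CG1691, X, 10686541 to 10715817) fell by 2.46 ± 0.16 (237 ± 3.21 against 1301 ± 211 CPM, adjusted p = 2.5e-05). Imp belongs to the Kenyon cell list and not to the octopaminergic list. Inputs in Tdc2 and R57C10 were 187 and 236 CPM for Vmat, 105 and 118 CPM for VGlut, and 242 and 256 CPM for Imp. With scaling by enrichment the log2 folds were -1.22, -1.14 and -1.43, with adjusted p = 0.0024, 0.0028 and 0.0012.

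Octopaminergic genes had a median of -0.43 with 3 of 7 lower over all genes and 4 lower adjusted over the list alone (adjusted p = 0.0032, and adjusted p = 0.461 with an estimated correlation), and the median was 0.05 with scaling by enrichment. The tyramine beta-hydroxylase gene Tbh (CG1543, X, 7889730 to 7920567) was the other member that fell (-0.46 ± 0.14, adjusted p = 0.032), but it did not pass with loess scaling by level (-0.21) or by enrichment (-0.25). The tyrosine decarboxylase gene Tdc2 (CG30446, 2R, 2572250 to 2577467) had 0.31 ± 0.15 (52.7 against 42.4 CPM, adjusted p = 0.165), with inputs of 73.2 and 57.7 CPM that can include the Tdc2 promoter in the driver. TyrR, Octbeta2R and Tdc1 had -0.43, -0.20 and 0.34 without passing.

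Hox and segmentation genes were lower in Tdc2, with 25 of 25 called, a median of -1.0 and adjusted p = 1.9e-24, and homeodomain identity genes had 50 of 57 lower, 52 adjusted over the list alone, and -1.02 (1.1e-40); both had adjusted p = 0.412 with an estimated correlation. With scaling by enrichment their medians were 0.06 (adjusted p = 0.547) and 0.13 (adjusted p = 0.074), and neither list passed. That scaling would remove a real loss along enrichment too, because both lists are strongly enriched in H3K27me3 in every library. Among the members, mirr fell by 1.46 (510 against 1405 CPM), nub by 1.16 (1390 against 3101 CPM), eve by 1.49, ftz by 1.64, vvl by 1.55 and the gap gene gt by 2.17, and with scaling by enrichment nub flipped to 0.06 and mirr, eve and vvl did not pass (-0.30, -0.42 and -0.47). Neural progenitor genes had -0.48 with 9 lower and 2 higher (5.2e-05; adjusted p = 0.412 with an estimated correlation), and 0.07 with scaling by enrichment. Kenyon cell genes had -0.26 with 9 lower and 3 higher (0.024; adjusted p = 0.588 with an estimated correlation), and flipped to 0.13 with loess scaling by level. The genes ey, toy and dac fell by 0.87 ± 0.17, 0.63 and 0.61, and with scaling by enrichment ey had -0.79 (adjusted p = 0.020) while toy and dac flipped to 0.28 and 0.30.

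**Figure D2:**
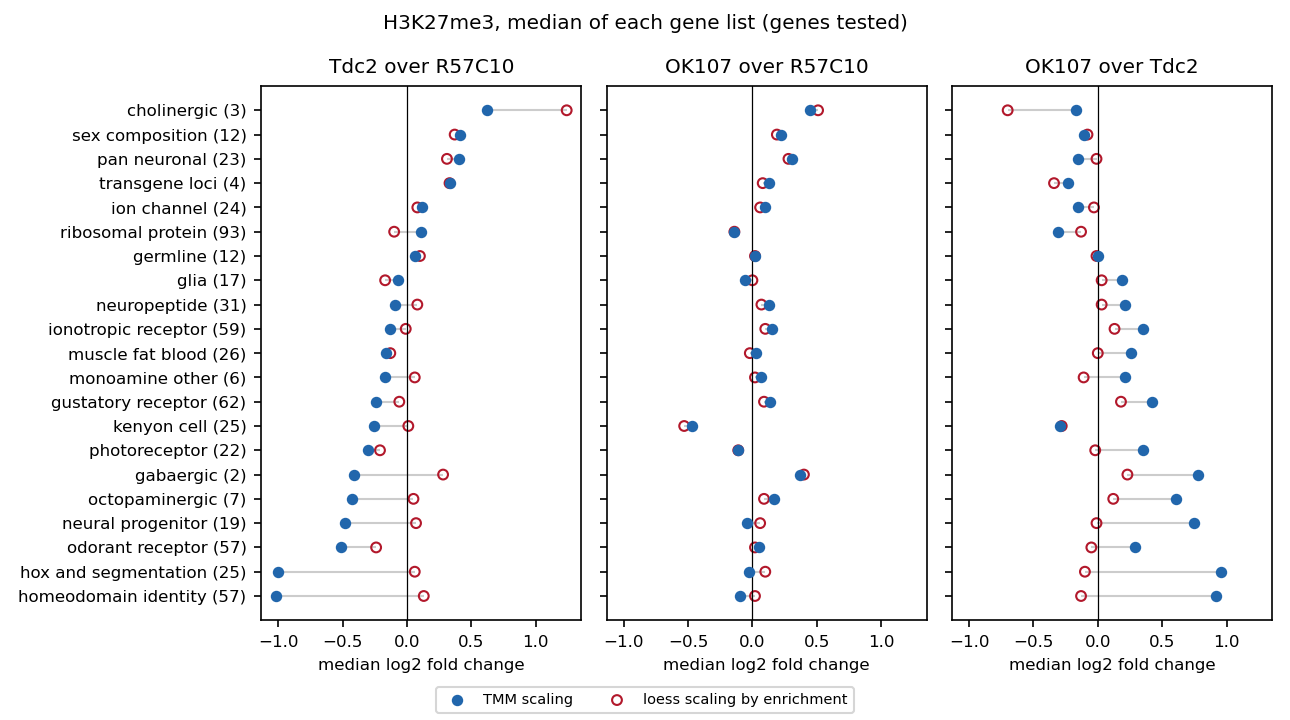
Median log2 fold of H3K27me3 for the 21 lists in the 3 comparisons of lines, with filled symbols for TMM and open symbols for scaling by enrichment. Hox and homeodomain lists move from about 1 log2 unit below 0 to near 0, crossing it, in Tdc2 over R57C10, while Kenyon cell genes stay below 0 in OK107 over R57C10.

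Pan-neuronal genes were higher in Tdc2, with a median of 0.40 and 10 of 23 called, 16 adjusted over the list alone (adjusted p = 1.9e-07, and adjusted p = 0.412 with an estimated correlation). Their median was 0.31 with scaling by enrichment (adjusted p = 3.4e-04). The rise was at levels below input, with median log2 ratios of H3K27me3 to input of -1.02 and -1.13 in R57C10 and -0.60 and -0.67 in Tdc2. The sodium pump subunit nrv3 rose by 1.05 ± 0.15 (59.3 against 28.7 CPM), Syt1 by 0.81, unc-13 by 0.75 and n-syb (CG17248, 3L, 1630348 to 1637767) by 0.55 ± 0.15, although n-syb did not pass with scaling by enrichment (0.40). Of the 3 cholinergic genes (median 0.62, 0.0096; adjusted p = 0.461 with an estimated correlation) the vesicular acetylcholine transporter gene VAChT (CG32848, 3R, 14531174 to 14544638) rose by 0.76 ± 0.15 (392 ± 22.5 against 231 ± 38.1 CPM, adjusted p = 0.0029). Choline acetyltransferase (Cha, CG12345), whose gene overlaps VAChT and may share its reads, rose by 0.62 ± 0.15 (665 against 433 CPM), and the choline transporter CG7708 had 0.16. With scaling by enrichment the cholinergic median was 1.24, with all 3 genes called higher (adjusted p = 0.0018 for the list).

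Other genes that rose were Lgr3, a relaxin-type receptor (CG31096, 3R, 21491531 to 21502938), by 1.25 ± 0.13 (200 ± 5.07 against 84 ± 0.449 CPM, adjusted p = 7.1e-05), and the adhesion gene Dscam2 (CG42256, 3L, 7152415 to 7183017) by 1.20 ± 0.13 (404 against 176 CPM). Dopa decarboxylase (Ddc, CG10697, 2L, 19116480 to 19120300) rose by 1.12 ± 0.17 (56.8 ± 7.84 against 26.2 ± 0.0859 CPM), and the Wnt pathway factor pan (CG34403, chromosome 4, 90287 to 134454) by 1.19 ± 0.15. The dosage compensation RNA roX1 (CR32777, X, 3752973 to 3756720) rose by 1.14, and the pheromone receptor Or67d by 1.11. The median log2 ratio of the Tdc2 gene-body input to that of R57C10 on X was 0.13, below 0 for 353 of 2262 genes. The odorant-binding proteins Obp99b (CG7592, 3R, 25541976 to 25542532) and Obp99d fell by 2.52 and 2.26, the odorant receptors Or23a and Or98b by 2.10 and 2.08, the phototransduction genes inaD and Arr2 by 1.83 and 1.76, and Gad1, which makes GABA, by 0.97, which scaling by enrichment flipped to 0.12.

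Odorant receptors had a median of -0.51 with 26 of 57 lower and 5 higher (adjusted p = 1.3e-04), gustatory receptors -0.24 with 20 of 62 lower (0.0018) and photoreceptor genes -0.30 with 8 of 22 lower (2.8e-04), and each of the 3 had adjusted p = 0.412 with an estimated correlation. The first 2 did not pass with scaling by enrichment, at -0.24 (adjusted p = 0.074) and -0.06 (adjusted p = 0.273), and photoreceptor genes had -0.21 (adjusted p = 0.048). Muscle, fat body and blood genes had -0.16 (0.017; adjusted p = 0.461 with an estimated correlation), glial genes -0.07 (0.0496; adjusted p = 0.477 with an estimated correlation) and sex-limited genes 0.41 (0.0496; adjusted p = 0.576 with an estimated correlation). With scaling by enrichment these had -0.13 (adjusted p = 0.206), -0.17 (adjusted p = 0.226) and 0.37 (adjusted p = 0.048), and loess scaling by level flipped the glial median to 0.02. Ionotropic receptors, ribosomal proteins, ion channels and neuropeptides had -0.13, 0.11, 0.12 and -0.09 without passing, and ribosomal proteins flipped to -0.10 with scaling by enrichment. Ion channels passed with loess scaling by level (0.37, 11 higher and 4 lower, adjusted p = 0.0104) but not with scaling by enrichment (0.08, adjusted p = 0.341). Germline genes had median 0.06 and mean -0.03 with a positive test, other monoamine genes median -0.17 and mean 0.01 with a positive test, and transgene loci 0.33. GABAergic genes, with 2 members and no test, had -0.41, which flipped to 0.28 with scaling by enrichment.

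In all, 2870 of 14585 genes were called, 722 higher and 2148 lower, and 912 with scaling by enrichment, 411 higher and 501 lower, of which 716 were shared. The share of higher calls was 25.2% with TMM, 39.3% with loess scaling by level and 45.1% with scaling by enrichment, and with total count scaling 5334 genes were called, 3960 of them higher. Without R57C10 late 1836 genes were called, and without Tdc2 early 4629, without Tdc2 late 4324. Total count scaling shifted the median of all genes to 0.40. On simulated data the fit recovered 75% of 2-fold and 98% of 4-fold changes, with 15 false calls.

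Kenyon cells and octopaminergic neurons were compared directly by OK107 against Tdc2 in H3K27me3, with 1 and 2 libraries. The gene ey was lower in OK107 (-2.52 ± 0.24, 159 against 909 ± 43.9 CPM, adjusted p = 7.8e-05), with inputs of 174 and 270 CPM, and had -3.56 with scaling by enrichment. Vmat, VGlut and Imp were higher in OK107 by 2.04 ± 0.18 (734 against 179 CPM), 2.04 ± 0.17 (530 against 129 CPM) and 1.97 ± 0.17 (930 against 237 CPM), with adjusted p = 7.5e-05 for Vmat. Of these, Imp is on the Kenyon cell list. The Wnt antagonist nkd (CG11614, 3L, 18996832 to 19038431) was higher by 2.18 ± 0.17 (1399 against 310 CPM), eloF (CG16905, 3R, 5639883 to 5640880) by 2.53 ± 0.22 (71.8 against 12.4 CPM) and Dhc36C by 2.11 (1020 against 237 CPM). The gene Gr21a (CG13948, 2L, 780482 to 782885) was higher by 1.98, the tetraspanin Tsp33B (CG14936, 2L, 11791025 to 11792365) by 2.20, and the paralogous P450 genes Cyp4p1 (CG10842, 2R, 5127548 to 5129642) and Cyp4p2 by 2.21 and 2.08.

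Besides ey, the lower genes in OK107 included Lgr3 (-1.22), emc (-1.54), pgant2 (-1.10), Ddc (-1.09), the Kenyon cell gene jdp (-0.88), unc-13 (-0.74) and nrv3 (-0.74). The genes pan, Pur-alpha, CaMKI and cals fell by 1.70, 1.27, 1.25 and 1.12, and all lie on chromosome 4, where the OK107 input was low. Kenyon cell genes had a median of -0.29 with 2 lower and 3 higher, and 5 lower adjusted over the list alone (adjusted p = 0.0085, and adjusted p = 0.572 with an estimated correlation). That median was -0.28 with scaling by enrichment, with 9 lower and 1 higher (adjusted p = 4.8e-05). Loess scaling by level gave the Kenyon cell genes a median of -0.68, with most members called lower. Octopaminergic genes had 0.61 with 4 of 7 higher, 5 adjusted over the list alone (4.4e-04; adjusted p = 0.472 with an estimated correlation), and 0.12 with scaling by enrichment (adjusted p = 0.106). Octbeta2R, TyrR and VGAT had 0.81, 0.61 and 0.97.

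Hox and segmentation genes had a median of 0.96 with 23 of 25 higher (adjusted p = 9.3e-18), homeodomain genes 0.92 with 48 of 57 higher (5.4e-28) and neural progenitor genes 0.75 with 11 higher (1.2e-04). With scaling by enrichment these 3 medians were -0.10, -0.13 and -0.01, and none of these lists passed. All 3 had adjusted p = 0.472 with an estimated correlation. The gustatory receptors had 0.42 with 18 higher (6.9e-05), ionotropic receptors 0.35 with 20 higher and 2 lower (1.9e-04) and photoreceptor genes 0.35 with 9 higher (0.0089), with adjusted p = 0.472 with an estimated correlation for each. Odorant receptors had 0.29 with 16 higher and 2 lower (0.0038; adjusted p = 0.572 with an estimated correlation), and scaling by enrichment flipped them to -0.05 and photoreceptor genes to -0.02. Pan-neuronal genes had -0.15 (0.035), ribosomal proteins -0.31 (0.0031) and transgene loci -0.23 (0.0038), again with adjusted p = 0.472 with an estimated correlation. With scaling by enrichment, gustatory receptors had 0.18 (adjusted p = 0.0046), while ionotropic receptors (0.13), pan-neuronal genes (-0.01), ribosomal proteins (-0.13) and transgene loci (-0.34) did not pass. Ion channels had median -0.15 and mean 0.03 and other monoamine genes median 0.21 and mean 0.01, both with a negative test that did not pass. With loess scaling by level the ion channel list passed at a median of -0.35, with more members lower than higher. With scaling by enrichment it had -0.03 and did not pass.

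The calls numbered 2249, 2036 higher in OK107 and 213 lower, or 90.5% higher, against 71.1% with loess scaling by level and 68.9% with scaling by enrichment, which called 665. The count was 4224 without Tdc2 early and 3826 without Tdc2 late. With total count scaling, which shifted the median of all genes to -0.43, there were 1271 higher and 2447 lower. On simulated data the fit recovered 56% of 2-fold and 95% of 4-fold changes.

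In windows of 10 kb, without a test and with the Tdc2 libraries pooled, H3K27me3 was at least 1.0 log2 unit higher in OK107 in 459 regions covering 13320 kb and higher in Tdc2 in 23 regions covering 450 kb, among 12040 windows above the median. The span of log2 H3K27me3 over input across genes was 2.25 in OK107 and 1.57 and 1.67 in Tdc2, and windows were not scaled for it. The region with the strongest excess in Tdc2 held ey (chromosome 4, 715001 to 765000), at a mean of -2.03, with H3K27ac at 1.28 and input at -0.46. Regions higher in OK107 lay over Vmat (2R, 9400001 to 9435000; 2.09, H3K27ac -1.43), the Obp99 cluster (3R, 25505001 to 25550000; 1.87), Imp (X, 10685001 to 10730000; 1.85), eloF and Teh1 (3R, 5630001 to 5665000; 1.84), nkd (1.82) and VGlut (2L, 2380001 to 2420000; 1.79). The longest, 260 kb, held the splicing factor mbl (2R, 13035001 to 13295000; 1.81). Window folds of H3K27me3 and H3K27ac had a rank correlation of -0.217 across windows, which overlap and are not independent.

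**Figure D3:**
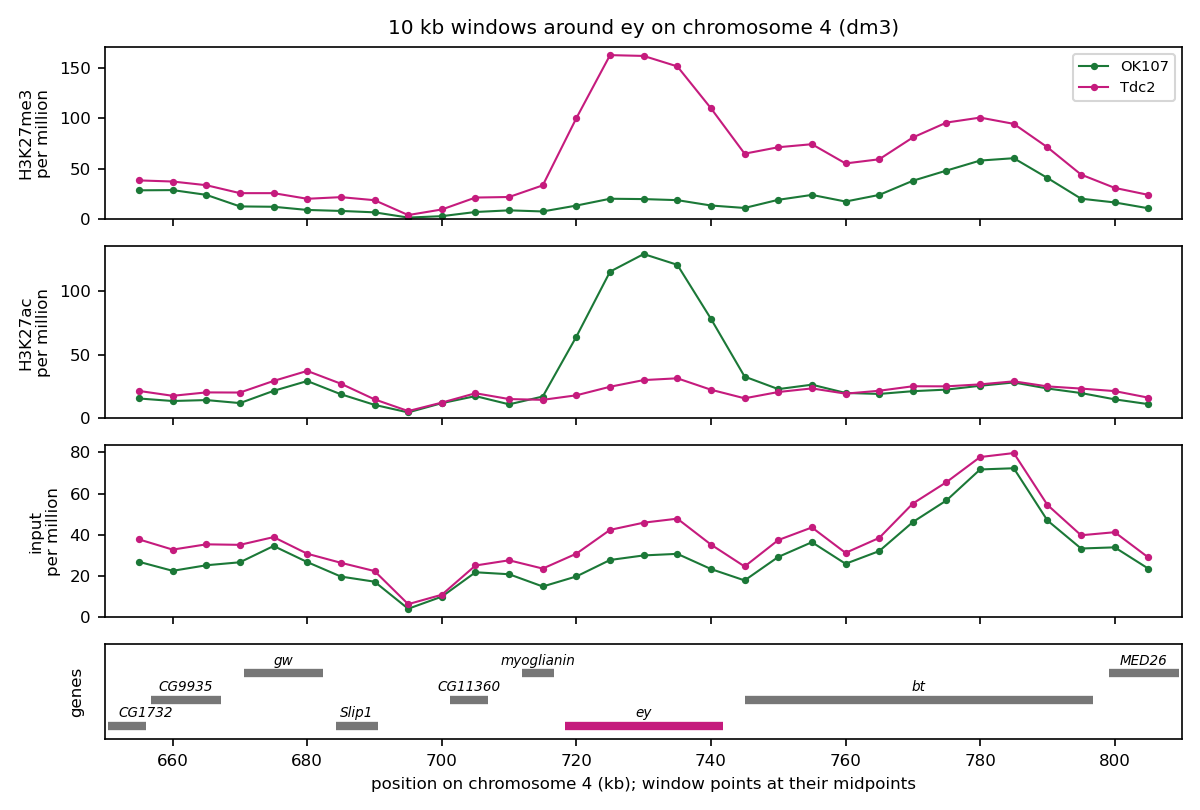
H3K27me3, H3K27ac and input in overlapping 10 kb windows around ey on chromosome 4, scaled to library size, for OK107 and Tdc2, with genes below. H3K27me3 is low and H3K27ac high in OK107 over ey, and the OK107 input is below that of Tdc2.

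For H3K27ac at promoters, OK107 against R57C10 asked which promoters are more or less active in Kenyon cells, with 1 and 2 libraries. The ey promoter rose 4.43-fold, with an error of 0.27 log2 (254 against 57.3 ± 0.792 CPM, adjusted p = 1.4e-11), with inputs of 59 and 69.1 CPM. With scaling by enrichment its log2 fold was 1.77 (adjusted p = 1.5e-07), and the folds that follow are log2 as well. The homeobox genes toe (CG10704, 3L, 12415608 to 12425768) and Lim3 (CG10699, 2L, 19079779 to 19106272) rose by 1.91 and 1.84 ± 0.29 (121 against 33.8 CPM for Lim3, adjusted p = 5.3e-07). The POU factor acj6 (CG9151, X, 15246390 to 15272487), known from olfactory neurons, fell by 1.74 ± 0.32 (12.7 against 42.4 CPM, adjusted p = 1.4e-05). The signalling genes dpp and hh rose by 1.28 and 1.23, eve by 1.22, ftz by 1.20, ttk by 1.15 and the hormone gene ETH by 1.20.

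Pan-neuronal promoters had a median of -0.48 with 6 of 23 lower (adjusted p = 1.0e-06, and adjusted p = 0.83 with an estimated correlation), and -0.33 with scaling by enrichment (adjusted p = 0.0011). The synaptobrevin gene n-syb fell by 1.41 ± 0.28 (78.8 against 209 ± 19.2 CPM, adjusted p = 7.8e-05), with inputs of 47 and 69.4 CPM that can include the n-syb fragment of the R57C10 driver. Snap25 (CG40452, 3L, 24067329 to 24292305) fell by 1.44, stnB by 1.03, Rbp9 by 1.02, the Kenyon cell gene Pka-C1 by 1.01, and exd by 1.57 with inputs of 8.43 and 21.5 CPM. The trehalase gene Treh fell by 1.20 but had 0.68 for its isoform with the largest input. Hox and segmentation genes had a median of 0.62 with 8 higher, 11 adjusted over the list alone (3.5e-04), homeodomain genes 0.35 with 12 higher and 3 lower (0.0039), muscle, fat body and blood genes 0.47 with 4 higher (0.0065) and ribosomal proteins -0.18 with 0 called (0.0065). These 4 lists had adjusted p = 0.83 with an estimated correlation, and neuropeptides, at 0.25 with 3 higher (0.012), had adjusted p = 0.85 with an estimated correlation. None of these 5 passed with scaling by enrichment, with Hox and segmentation genes at 0.15 (adjusted p = 0.286), homeodomain genes at 0.02 (0.616), muscle, fat body and blood genes at 0.12 (0.493), ribosomal proteins at -0.07 (0.432) and neuropeptides at 0.22 (0.149). Kenyon cell genes had 0.15 with 1 higher and 1 lower, octopaminergic genes a median of 0.03 and a mean of -0.03 with 0 called, and cholinergic genes -0.42 with 0 called.

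H3K27ac was called at 1543 of 14710 promoters, 1091 higher and 452 lower, of which 70.7% were higher, against 46.1% with loess scaling by level and 59.5% with scaling by enrichment. DESeq2 called 176, the model of these lines alone 869, the input offset 630 and scaling by enrichment 642. On simulated data the fit recovered 54% of 2-fold and 100% of 4-fold changes.

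In Tdc2 against R57C10, with 1 and 2 libraries, H3K27ac was asked to show promoters active in octopaminergic neurons. The Tdc2 promoter rose by 1.19 ± 0.28 (157 against 68.9 ± 6.42 CPM, adjusted p = 2.9e-04), with inputs of 79.3 and 81 CPM, and by 1.33 with scaling by enrichment (adjusted p = 9.5e-04). Imp rose by 1.72 ± 0.28 (73.7 against 22.5 CPM, adjusted p = 1.1e-07), and by 1.16 with scaling by enrichment (adjusted p = 0.0094). VGlut rose by 1.43 ± 0.29 (94.8 against 35.1 CPM, inputs 75.7 and 54.5 CPM) and Vmat by 1.15 (54.8 against 24.7 CPM, inputs 43.3 and 69 CPM), and with scaling by enrichment they had 0.79 and 0.28 without passing. The pan promoter fell by 1.68 ± 0.31 (44.3 against 142 CPM, adjusted p = 2.7e-06).

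Octopaminergic genes had a median of 0.87 with 4 of 7 higher and 1 lower, the same adjusted over the list alone, and did not pass as a list (adjusted p = 0.23); Tdc1 had 0.87 and Octbeta2R -1.05. All 3 cholinergic promoters fell, Cha by 1.15 (43.1 against 95.9 CPM), VAChT by 1.12 and CG7708 by 1.01, with a median of -1.12 (adjusted p = 0.0061, and adjusted p = 0.73 with an estimated correlation). Their median was -0.97 with scaling by enrichment (adjusted p = 2.8e-04), with 0 of the 3 called. Cha and VAChT are overlapping genes, and whether their promoter windows share reads was not checked, so these promoters may not be independent. Pan-neuronal promoters had -0.60 with 8 of 23 lower, 11 adjusted over the list alone (9.8e-06; adjusted p = 0.69 with an estimated correlation), and -0.19 with 0 called with scaling by enrichment (adjusted p = 0.059), among them n-syb at -1.17 ± 0.27 (93.3 against 209 ± 19.2 CPM), Snap25 at -1.19 and nrv3 at -1.03. The homeobox gene toe rose by 1.99 ± 0.29 (35.1 against 9.02 CPM) and scro fell by 1.88, and both kept their calls with scaling by enrichment, as did TwdlV (1.15), Itp-r83A (0.97), mRpL23 (-1.52), Or67c (-1.42) and kek2 (-1.24).

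Hox and segmentation promoters had a median of 0.98 with 16 higher (adjusted p = 9.8e-06), homeodomain promoters 0.66 with 27 higher and 3 lower (9.8e-06), muscle, fat body and blood genes 0.79 with 15 higher and 1 lower (2.4e-05) and ribosomal proteins -0.56 with 27 lower and 1 higher (4.5e-09). These 4 lists had adjusted p = 0.62 with an estimated correlation, and scaling by enrichment flipped the Hox and homeodomain medians to -0.02 and -0.12, and gave 0.08 (adjusted p = 0.919) and -0.17 (adjusted p = 0.053) for the other 2. Ionotropic receptors had 0.49 with 23 higher (0.0012) and neuropeptides 0.52 with 12 higher (0.0071), both with adjusted p = 0.73 with an estimated correlation, and with scaling by enrichment the ionotropic median flipped to -0.13 and that of neuropeptides was 0.11 (adjusted p = 0.50). Kenyon cell promoters had -0.26 with 1 higher and 2 lower.

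There were 4096 calls among 14710 promoters, 2966 higher and 1130 lower, but the median log2 fold ran from 0.90 in the lowest 20% of promoters by level to -0.46 in the highest. Loess scaling by level called 1094 promoters, scaling by enrichment 134 and DESeq2 2123, and the share of higher calls was 72.4% with TMM, 44.9% with loess scaling by level and 53% with scaling by enrichment. On simulated data the fit recovered 48% of 2-fold and 100% of 4-fold changes.

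**Figure D4:**
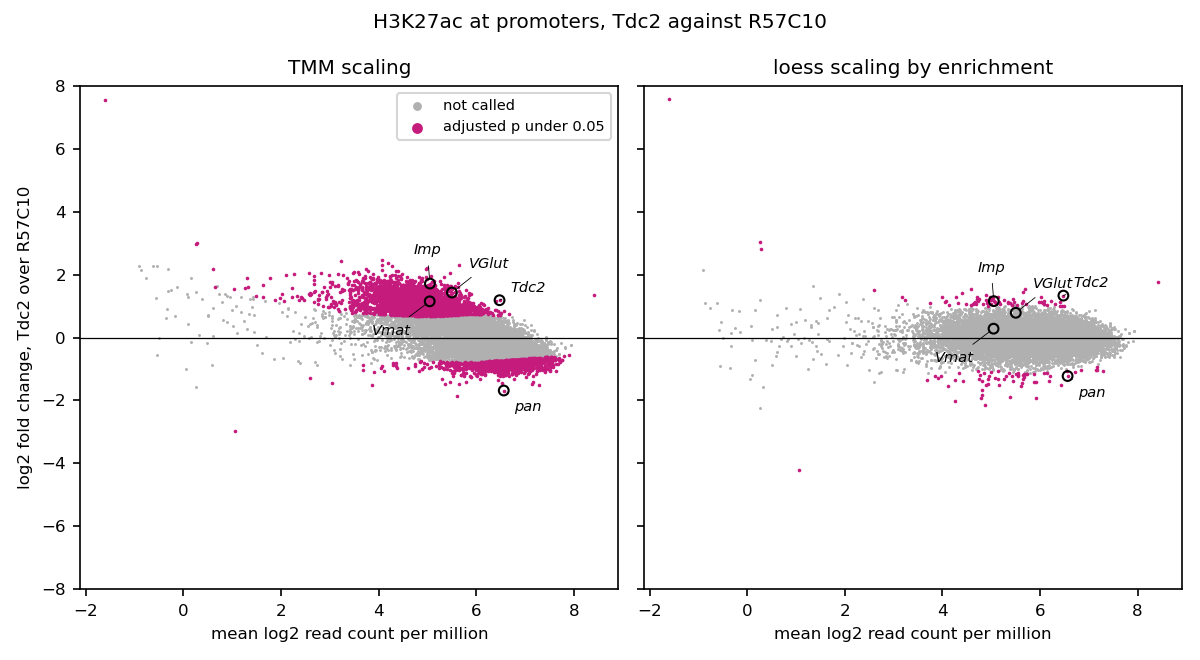
Log2 fold of promoter H3K27ac in Tdc2 over R57C10 against mean log2 CPM, with TMM on the left and scaling by enrichment on the right, and called promoters in colour. The downward trend on the left, positive at weak promoters and negative at strong promoters, is absent on the right, where Tdc2, Imp and pan remain called.

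H3K4me3 was used to ask the same of promoters in the same 2 lines, each with 1 library against 2 of R57C10. The ey promoter in OK107 had 2.09 ± 0.53 (246 against 57.5 ± 7.26 CPM), which did not pass (adjusted p = 0.58) but had 2.26 with loess scaling by level (adjusted p = 4.0e-15). The Tdc2 promoter in Tdc2 had 3.08 ± 1.15 (62.3 against 7.38 ± 2.87 CPM, adjusted p = 0.653), with inputs of 80.2 and 82 CPM, and 1.62 with loess scaling by level (adjusted p = 0.040). By edgeR 0 of 14732 promoters were called in Tdc2, with 655 at unadjusted p under 0.05, 1 by DESeq2, 161 with total count scaling and 297 with loess scaling by level. In OK107 the single promoter called was mthl8 (CG32475, 3L, window 22448 to 23448), a Methuselah-like receptor gene, whose input also differed, with 331 reads in OK107 and 0 in R57C10. There 68 promoters had unadjusted p under 0.05, DESeq2 called 5, total count scaling 13 and loess scaling by level 138.

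Pan-neuronal promoters had a median of -1.04 in Tdc2 with 3 lower adjusted over the list alone (adjusted p = 3.1e-06, and adjusted p = 0.70 with an estimated correlation) and -0.50 in OK107 (adjusted p = 3.9e-14, and adjusted p = 0.84 with an estimated correlation). Their medians in Tdc2 and OK107 were -0.52 and -0.33 with scaling by enrichment, and -0.40 and -0.36 with loess scaling by level. Hox and segmentation genes had 1.25 (1.1e-04), homeodomain genes 0.84 (0.0017), neural progenitor genes 1.69 (5.7e-04), muscle, fat body and blood genes 1.74 (2.3e-04) and ion channels -0.93 (0.0066) in Tdc2, each with adjusted p = 0.70 with an estimated correlation. The median fold of all promoters in Tdc2 ran from 1.59 in the lowest 20% by level to -0.88 in the highest, and with scaling by enrichment these 5 medians were 0.26, 0.32, 0.28, 0.05 and -0.28, of which that of muscle, fat body and blood genes did not pass (adjusted p = 0.662). Odorant, gustatory and ionotropic receptors had 1.68, 1.63 and 1.76, neuropeptides 1.56, glial genes 1.34 and ribosomal proteins -0.79, again with adjusted p = 0.70 with an estimated correlation. Scaling by enrichment flipped the 3 receptor lists to -0.13, -0.19 and -0.02 and neuropeptides to -0.15, and loess scaling by level flipped glial genes to -0.04 and ribosomal proteins to 0.02. In OK107, homeodomain genes had 0.60 (2.7e-11), Hox and segmentation genes 0.65 (7.7e-11), neural progenitor genes 0.45 (6.8e-05), ion channels -0.28 (7.1e-04), cholinergic genes -0.55 (0.031) and transgene loci 1.11 (0.035), and each had adjusted p = 0.84 with an estimated correlation. Scaling by enrichment gave ion channels -0.21 (adjusted p = 0.168) and cholinergic genes -0.51 (adjusted p = 0.164). Gustatory receptors had 0.25 (0.047; adjusted p = 0.87 with an estimated correlation) and flipped to -0.07 with scaling by enrichment. Kenyon cell genes in OK107 had 0.22 with ey alone called when adjusted over the list alone (adjusted p = 0.24), and 0.21 with scaling by enrichment (adjusted p = 0.0024).

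The median of all promoters in H3K4me3 was 0.50 in Tdc2, -0.12 with RLE and 0.93 with total count scaling, and in OK107 0.09, -0.21 and 0.02. On simulated data the fit gave 0% of 2-fold and 6% of 4-fold changes recovered in Tdc2 and 0% of both in OK107.

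For OK107 against Tdc2 at promoters, which had 1 library on each side and the same date tag, no test was made, and differences were set against those between R57C10 replicates. The ey promoter was higher in OK107 in H3K4me3 (246 against 53.1 CPM, log2 difference 2.19) and in H3K27ac (254 against 44.7 CPM, 2.48). The Tdc2 promoter was higher in Tdc2 in H3K4me3 (10.3 against 62.3 CPM, -2.48), as was that of Tbh (8.55 against 31.5 CPM, -1.77), and in H3K27ac Tdc2 had 84.8 against 157 CPM (-0.88), which lay beyond the bound only after a running median by level was subtracted (-1.06). In H3K27ac the Kenyon cell genes pros (157 against 63.3 CPM, 1.29) and dac (58 against 24.4 CPM, 1.22) were higher in OK107. VGlut (35.8 against 94.8 CPM, -1.38) and Imp (32 against 73.7 CPM, -1.18) were higher in Tdc2, with Imp inside the bound after that subtraction (-0.86). Imp is itself on the Kenyon cell list, of which 3 promoters lay beyond the bound higher in OK107 and 1 higher in Tdc2. Kenyon cell genes had a median of 0.53 in H3K4me3 and 0.22 in H3K27ac before the subtraction, at percentiles 100 and 99.27 of random lists matched on level. These medians were 0.42 and 0.27 after it. Octopaminergic genes had -0.86 and -0.61 before the subtraction, at percentiles 11.95 and 0.02, but -0.06 and -0.24 after it. Other lists also lay near or beyond the ends of the random lists, in H3K4me3 glial genes (99.23), ion channels (99.33), ionotropic receptors (0) and odorant receptors (0.01), and in H3K27ac ribosomal proteins (100), cholinergic genes (98.95), gustatory receptors (0), ionotropic receptors (0.06), odorant receptors (0.18) and transgene loci (0.43). In H3K4me3 501 of 14732 promoters lay beyond the bound of 1.72, 12 of them higher in OK107, and 128 beyond 1.11 after the running median was subtracted, 103 of them higher in OK107. In H3K27ac 568 of 14710 lay beyond 0.88, 37 of them higher in OK107, and 130 beyond 0.94 after that subtraction, 63 of them higher in OK107. Between the R57C10 replicates, 1.0% of promoters in H3K4me3 and 1.01% in H3K27ac lie beyond these bounds by construction. The counts after the subtraction were below these shares.

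Across genes, again not independent replicates, H3K4me3 and H3K27ac had rank correlations over input of 0.776 in R57C10, 0.75 in OK107 and 0.665 in Tdc2. H3K27me3 correlated with H3K4me3 at -0.64, -0.71 and -0.535 and with H3K27ac at -0.492, -0.579 and -0.448. H3K4me3 and H3K27ac were divided by the promoter input and H3K27me3 by the gene-body input. Without this division the correlations of H3K27me3 were -0.098, -0.129 and -0.010 with H3K4me3, and -0.059, -0.077 and -0.009 with H3K27ac. Those of H3K4me3 with H3K27ac were 0.676, 0.589 and 0.476. Gene-body counts without the input are not corrected for gene length. Ribosomal proteins were at percentile 100 of random lists for H3K4me3 and H3K27ac and at 0 for H3K27me3 in every library. The Hox and segmentation genes were at percentile 100 for H3K27me3 and 0 for H3K27ac in every library, and their median log2 ratio of H3K27me3 to input was 2.39 and 2.77 in R57C10, 2.37 in OK107, and 1.55 and 1.57 in Tdc2.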

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

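The tests of chromosome 4 copies, of a heterochromatin bias and of how many acetylation calls remain after loess scaling by level were chosen only after the results were seen; the other tests of this part were set down before their values were known.

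The first pattern was the fall of H3K27ac folds in Tdc2 over R57C10 with promoter level. The span of log2 mark over input between the 10th and 90th percentile of promoters was 1.69 in Tdc2, against 3.15 and 3.17 in R57C10 and 2.51 in OK107, which is in line with weaker enrichment over background in the Tdc2 library. Thinning to equal totals left the difference between the lowest and highest 20% of promoters at 1.31. Thinning keeps the expected share of reads per promoter, so it could hardly move this difference, and effects of a small library stay open. After loess scaling by level 14.3% of the called promoters stayed called with the same sign, but that scaling sets the median fold to 0 at every level and would remove a real trend too. Acetylation that differs between the cell types along promoter level therefore cannot be told apart from weaker enrichment.

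The second pattern was the low OK107 input on chromosome 4, which holds ey, toy and pan. Genes of the heterochromatic scaffolds were low as well, with a median log2 input ratio to R57C10 of -0.28 against -0.55 on chromosome 4, and their quartiles of -0.54 and 0.02 overlapped those of chromosome 4, so a bias against heterochromatin stays open. Fewer copies of chromosome 4 in the OK107 flies cannot be told apart from it, since OK107 over R57C10 had -0.54 in H3K4me3 and -0.81 in H3K27ac but -0.07 in H3K27me3. In the same marks Tdc2 over R57C10 had -0.18, -0.56 and 0.54. OK107 over Tdc2 had -0.28, -0.15 and -0.64, all in the direction of fewer copies, but no limit was set for that comparison. The limit for that explanation was set on OK107 over R57C10, where the H3K27me3 value of -0.07 fell short of it. No biological explanation was tested, and base composition was not tested.

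The third pattern was the lower H3K27me3 of Hox, segmentation and homeodomain genes in Tdc2 than in R57C10. Among random lists matched on H3K27me3 over input in OK107, their medians lay at percentiles 81.98 and 91.41, which is in line with weaker enrichment in the Tdc2 libraries rather than a change special to these genes. Thinning left the Hox median at -0.98. Thinning keeps the expected share of reads per gene, so it could hardly move this median, and effects of small libraries stay open. The early Tdc2 library minus OK107, of the same date tag, had -1.0, which argues against the tag. In the same matching, cholinergic genes lay at percentile 100, sex-limited genes at 99.87, pan-neuronal genes at 99.49, ribosomal proteins at 0.73 and odorant receptors at 0.17, the cause of which was not tested. A loss of Polycomb marking in octopaminergic neurons themselves stays open.

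At some promoter windows outside the comparisons of marks, the inputs of the lines differed widely. The neighbouring genes CG12491 (2R, 19637709 to 19638709) and CG34105 (2R, 19636876 to 19637876) had 161 and 125 reads in the Tdc2 input, 37 and 35 in R57C10, and 2 and 0 in OK107. The Y-linked phosphatase gene Pp1-Y1 had 187 reads in the R57C10 input, 179 in OK107 and 1 in Tdc2. The gene mthl8 had 331 reads in the OK107 input, 0 in R57C10 and 4 in Tdc2.

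In H3K27me3, 84 genes were called in opposite directions in Tdc2 and OK107 against R57C10, with the difference between the lines itself called, and all 84 were lower in Tdc2 and higher in OK107. With scaling by enrichment 1 of them, Tsp33B, kept all of these calls. The log2 difference of OK107 over Tdc2 was 2.53 for eloF, 2.21 for Cyp4p1, 2.20 for Tsp33B, 2.18 for nkd, 2.11 for Dhc36C, 2.08 for Cyp4p2, 1.98 for Gr21a and 1.77 for hbs.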

How the results depend on the processing

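The scalings by loess, the restriction to the large arms and the running median by level were chosen only after the results were seen. No paired analysis was possible because the columns carry date tags and no replicate number, and no 2 lines shared more than 1 date tag in a mark.

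Calls of H3K27me3 in Tdc2 over R57C10 kept their number within 1.5 times under RLE, DESeq2, the input offset and loess scaling by level. They numbered 5334 with total count scaling, 912 with scaling by enrichment, 1836 without R57C10 late, 4629 without Tdc2 early and 4324 without Tdc2 late; the cause was not tested. In OK107 over R57C10 they numbered 146 with RLE, 634 with total count scaling, 978 with these lines alone, 505 with the input offset and 497 with loess scaling by level; the cause was not tested. Leaving out a library gave 847 and 651 for R57C10 early and late and 993 and 990 for Tdc2 early and late. For OK107 over Tdc2 they numbered 3718 with total count scaling, 665 with scaling by enrichment, 4224 without Tdc2 early and 3826 without Tdc2 late, and 2371 without R57C10 late; the cause was not tested.

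Calls of H3K4me3 in Tdc2 numbered 161 with total count scaling, 1 with DESeq2, 297 with loess scaling by level and 1 with scaling by enrichment, and in OK107 13, 5 and 138 with the first 3 of these; the cause was not tested. Calls of H3K27ac in Tdc2 numbered 2123 with DESeq2, 1094 with loess scaling by level and 134 with scaling by enrichment. In OK107 they numbered 176 with DESeq2, 869 with these lines alone, 630 with the input offset and 642 with scaling by enrichment; the cause was not tested. Leaving out an R57C10 library in these marks left no residual degrees of freedom, so only folds were compared. Across all genes, which are not independent replicates, these correlated with the folds of both replicates at 0.711 and 0.688 for H3K4me3 in OK107, 0.981 and 0.969 for H3K4me3 in Tdc2, 0.943 and 0.963 for H3K27ac in OK107, and 0.967 and 0.971 for H3K27ac in Tdc2.

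With an estimated correlation 0 lists passed in every comparison; the cause was not tested. With scaling by enrichment, 4 lists passed in H3K27me3 for Tdc2 over R57C10, 3 for OK107 over Tdc2, 7 in H3K4me3 for Tdc2, 3 in H3K27ac for Tdc2 and 1 for OK107. With loess scaling by level 4 passed in H3K4me3 for OK107, 5 in H3K27ac for Tdc2 and 1 for OK107; the cause was not tested.

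Some named genes reversed. In H3K27me3 of Tdc2 over R57C10, scaling by enrichment gave toy 0.28, dac 0.30, tey 0.20, pros 0.18 and Gad1 0.12, and loess scaling by level gave pros 0.14. Scaling by enrichment also gave bcd 0.02, pdm2 0.04, nub 0.06, dimm 0.08 and dsx 0.12; the cause was not tested. For OK107 over Tdc2 scaling by enrichment gave tey -0.23, Trh -0.01, srp -0.01 and Fbp1 -0.11, and Tk -0.01, dimm -0.08 and dsx -0.29; the cause was not tested. In H3K27ac of Tdc2 scaling by enrichment gave Ir52b -0.17, sc -0.02, kl-5 -0.28, kl-3 -0.14 and Ppr-Y -0.06, and loess scaling by level gave SerT -0.15. Treh had 0.68 in OK107 for its isoform with the largest input; the cause was not tested.

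Correlations of marks across genes changed without the input. H3K4me3 with H3K27ac had 0.676, 0.589 and 0.476 in R57C10, OK107 and Tdc2. H3K4me3 with H3K27me3 had -0.098, -0.129 and -0.010, and H3K27ac with H3K27me3 had -0.059, -0.077 and -0.009; the cause was not tested. In R57C10, leaving out the early or the late replicate gave -0.641 and -0.633 for H3K4me3 with H3K27me3, and -0.484 and -0.492 for H3K27ac with H3K27me3. For promoters of OK107 against Tdc2, 128 in H3K4me3 and 130 in H3K27ac lay beyond the bound after the running median was subtracted. These counts were below the share of promoters beyond the bound between R57C10 replicates. A window comparison of Tdc2 with R57C10 was not run, because R57C10 was not in the window table used, and pseudocounts for normalized values did not apply to counts.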

Other observations

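No test in this part decided between explanations, and the pairs of marks, regions and shares given here were chosen only after the results were seen.

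In OK107 over R57C10 14 genes fell in H3K27me3 and rose in H3K27ac, against 6.8 for independent calls, among them Hr51 (-1.16 and 1.30), amd (-0.84 and 1.49) and Lin29 (-0.94 and 0.88). In the other direction 17 genes, against 6.8, rose in H3K27me3 and fell in H3K27ac, among them hbs (1.33 and -1.17), fra (1.18 and -0.97), Syt4 (0.86 and -1.05) and beat-IIa (0.85 and -1.12). With scaling by enrichment these numbers were 4 against 2.5 and 5 against 3.1, and of the genes named, Hr51, hbs and beat-IIa kept both calls. In Tdc2 over R57C10 623 genes lost H3K27me3 and gained H3K27ac, against 434.9, 145 against 66.3 with loess scaling by level, and 12 against 2.3 with scaling by enrichment. Among them were Dup99B (-3.04 and 2.18), mir-10 (-2.26 and 2.10), dmrt99B (-1.95 and 1.96) and Imp (-2.46 and 1.72), while pan (1.19 and -1.68), nrv3 (1.05 and -1.03) and myoglianin (0.99 and -0.90) were among 112 genes, against 55.4, with the opposite pair, or 11 against 1.8 with scaling by enrichment. Of the genes named, Dup99B, dmrt99B, Imp and pan kept both calls with that scaling. Both pan and myoglianin lie on chromosome 4, whose 84 genes had medians of 0.54 in H3K27me3 and -0.56 in H3K27ac in Tdc2 over R57C10.

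A region around mir-276a and mir-276b (3L, 10310001 to 10385000) carried less H3K27me3 in OK107 than in Tdc2, at a mean log2 difference of -1.53, with H3K27ac at 0.65 and input at -0.32. Nearby regions at Or67c (3L, 10220001 to 10240000) and at can and Or67d (3L, 10260001 to 10290000) had -1.27 and -1.18. No test was made on windows.

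Reads of mthl8 were absent from R57C10 and present in OK107, at least 2330-fold higher in H3K4me3, 416-fold in H3K27ac and 255-fold in H3K27me3, beside the input difference. The gene Unc-115b, with no H3K27ac reads in R57C10, was at least 17.8-fold higher in Tdc2, but at a low level of 2.025 CPM in a single library.

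Promoter reads of H3K4me3 on the X chromosome, as a percentage of those on arms 2L, 2R, 3L and 3R together, were 13.408 and 15.506 in R57C10 early and late, 15.021 in OK107 and 14.982 in Tdc2. For H3K27ac the percentages were 13.668, 15.453, 15.131 and 15.065 in the same order, and for inputs 11.769, 12.997 and 13.116 in R57C10, OK107 and Tdc2.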
